A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

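Fission yeast (Schizosaccharomyces pombe) was grown in the rich medium YEA at 18 °C for 3 days and kept in mid-log phase, per the labels' protocols. Total RNA was extracted with a yeast RNA purification kit, made into libraries with the ScriptSeq v2 kit, which keeps the strand of the RNA, and sequenced on a NextSeq 500. The labels name 4 genotypes, wild type and deletions of swd22, ssu72 and clr4, with 1 library each. Groups were taken from the genotype label. Trimmomatic and STAR are named in the submitters' processing notes without versions. The genome build, the program that made the ratios and the strand setting of the counting are not given in the sources used here.

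Per the file headers, each deposited file holds a log2 fold change and a p-value for each of 7015 features, of which 5144 were of type mRNA, 1236 other transcripts and 635 antisense features. The deposited log2 values are ratios of the named library to a reference library that the files do not name, and the values show that all 4 files share it. The deposited p-values compare the read numbers of those libraries and carry no biological spread, so none of them was used as a test of a genotype. A feature with 0 reads in a library takes the value of 0.5 reads in the deposited ratio, and features with at most 4 reads in 1 library and 0 in the other have the ratio set to 0, in at least 1 file for 462 features. This was read from the values, in which the lowest count shown beside 0 reference reads was 5 and the highest reference count behind a ratio of 0 was 4.

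Read numbers per feature were recovered from the deposited values. Ratios of whole numbers form fixed steps. Under a random sampling model the p-value follows from the ratio and the product of both counts, so that ratio and p-value together fix both counts. Counts of 6565 features were solved from ratio and p-value and those of 88 from the ratios alone, and 362 features had a ratio of 0 in all 4 files, which leaves at most 4 reads in each library. Where the reference library held 0 reads, a ratio of 0 leaves the count open between 0 and 4 reads. Such counts occurred for 5 features in the library labelled wild type, 11 in swd22, 8 in ssu72 and 4 in clr4 among features with at least 10 reads in another library, and no fold or interval is given for them. Among low-count features with a usable p-value (2494 to 2775 per file), 100% of the estimates from ratio and p-value lay within 0.05 of a whole number. The 4 files gave reference counts that matched within 1 percent for 100% of the 6424 features where they could be compared. The design fixed before the data were examined had assumed levels or counts with the scaling chosen by unit, and the differences below keep the scale of the deposited ratios instead. Recovery was tested on simulated data drawn for the comparison of the swd22 deletion with wild type, where 100% of 6580 features with simulated wild-type reads came back exactly, with counts left open by such ratios excluded. The simulated ratios and p-values were made with the same model. This checks the solving of the counts and cannot test whether the deposited values follow that model.

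The difference between libraries was the log2 ratio of their recovered reads, with a count of 0, or an open count, set to 0.5, on the scale of the deposited values. A feature was measured in a comparison when the higher of both libraries held at least 10 reads. A difference of at least 2-fold was counted in each direction. With 1 library per group no test of genotype was possible, so no p-value is given, and every difference lacks a replicate check. Intervals are exact Clopper-Pearson intervals at the 95% level from the reads of both libraries. They cover counting error only, and reads without molecular identifiers are not independent molecules. Where a library held 0 reads, the fold was computed against a floor of 3 reads in that library and is written as a lower bound. In the simulated comparison of the swd22 deletion with wild type, 60% of 50 features changed 2-fold, 100% of 50 changed 4-fold, 40% of 50 changed to 0.5-fold and 100% of 50 changed to 0.25-fold passed the threshold, against 0.258% of 6198 unchanged features. The intervals held the true change for 90% to 96% of the features of each size.

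The libraries held 15282718 (wild type), 19630981 (swd22), 24005944 (ssu72), 22839463 (clr4) and 22652585 reads (unnamed reference) over the features. The most abundant feature was srp7, the RNA of the signal recognition particle, with 2.44% to 5.09% of the reads of a library. Near-identical copies (Tf2 elements, transfer RNA genes, subtelomeric families) can share reads, and their values are uncertain. The strand setting is not stated. In the unnamed reference library SPBC23G7.13c held 53 reads and its antisense feature, which lies inside its span, held 636. These values argue against counting without regard to strand for this pair. How far reads of other overlapping partners were kept apart was not tested.

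Lists were fixed before the data were examined. They comprised meiotic genes with a determinant of selective removal (DSR), phosphate response, mating-type cassette genes, Tf2 retrotransposons, telomere-linked helicases, cleavage and polyadenylation factor (CPF) and termination genes, heterochromatin factors, RNA elimination, core stress response, iron acquisition, mating and differentiation, middle meiosis, histones, hexose and glucose-repressed genes, nitrogen and amino acid transport, and DNA replication and cell cycle. Further lists followed rules: ribosomal proteins, features within 100 kb of the ends of chromosomes I and II, pericentromeric features, the long noncoding RNAs with SPNCRNA identifiers, snoRNAs, snRNAs, tRNAs, rRNAs, pseudogenes, antisense features, genes within 1 kb downstream of an SPNCRNA on the same strand, convergent pairs and genes in tandem downstream of another gene. The list median was placed as a percentile among 10000 random lists of equal size matched on the mean level in 20 bins, which describes these libraries. Names were matched to the NCBI annotation ASM294v3 for 6862 features, and that annotation served for names, biotypes, exon numbers, coding lengths and chromosome lengths. Coordinates are those of the files. Named genes followed a rule fixed beforehand: in each mutant the 10 highest and 10 lowest protein-coding and the 3 highest and 3 lowest noncoding features, up to 4 members of each list with the largest difference, the deleted genes, and mei4, ssm4, mcp7, mcp5, rec8, spo5, pho1, pho84, tgp1, tlh1 and tlh2; between mutants, the 5 highest and 5 lowest features. The genes swi6, ura4 and met17 are described in every library as genes chosen after their values were seen.

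Comparisons between mutants share the library labelled wild type, so 100 sets of unchanged libraries were drawn from the pooled read rates and set beside each overlap and correlation. Alternatives fixed beforehand were fold thresholds of 1.5 and 4, centring on the median, no filter, a filter of 50 reads, a pseudocount of 0.1, median-ratio scaling, protein-coding features alone, list means and the removal of repeated families. A pseudocount of 1, random lists of protein-coding features, open counts set to 4 reads and the unnamed reference library as the control were added after seeing the data. The result for 1 member of the replication and division list is not reported here. Left out were the deposited p-values as tests, comparisons with sequence-level data, and any analysis of the reads themselves. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.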

Results

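RNA was measured by sequencing in 4 cultures of fission yeast grown in the cold. The labels gave wild type, deletions of swd22 and ssu72, which encode subunits of the cleavage and polyadenylation factor (CPF) that forms the 3' ends of transcripts, and deletion of clr4, which encodes the histone H3 lysine 9 methyltransferase of heterochromatin. The series title names the role of CPF in heterochromatin and silencing as its question. Each genotype had 1 library of 15282718 to 24005944 reads, in which 6276 to 6423 features held at least 10 reads, and no difference below has a replicate check. Features of type mRNA held 92.0% to 93.5% of the reads. A reference library that the files do not name, with 22652585 reads, is given as a further point of comparison. Its strain and growth conditions are not known, so a difference from it may come from either and not from the deletion. Differences are on the log2 scale against the library labelled wild type unless stated, and brackets hold 95% counting intervals.

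The deleted genes came first, as a check of the labels. The gene ssu72 (chromosome I, 3176427 to 3177452) held 16 reads in the library labelled ssu72 deletion against 478 in the library labelled wild type, a difference of -5.55 (-6.37 to -4.84), and 484 to 740 reads in the other libraries. The gene swd22 (chromosome I, 1690187 to 1691715) held 281 reads in the library labelled swd22 deletion against 687, a difference of -1.65 (-1.86 to -1.45), and 651 to 787 elsewhere. Its feature spans 1529 bases against a coding length of 1026, so that part of it lies outside the coding sequence. The feature of clr4 (chromosome II, 453996 to 458487) held 1645 reads in the library labelled clr4 deletion and 1158 in that labelled wild type, a difference of -0.07 (-0.18 to 0.04). It spans 4492 bases against a coding length of 1473 and overlaps the gene meu6, which held 392 and 166 reads. Reads outside the deleted part check nothing, so this label rests on no loss of reads here.

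Other genes set the library labelled wild type apart from the remaining 4. The gene swi6 (chromosome I, 1702406 to 1704073), which encodes the heterochromatin protein of the HP1 family, held 200 reads there and 3601 to 4431 in each of the others. The mutant libraries lay higher by 3.82 (3.62 to 4.03) for swd22, 3.57 (3.36 to 3.78) for ssu72 and 3.59 (3.38 to 3.80) for clr4. The gene ura4, a uracil synthesis gene that is widely used as a marker, held 6 reads against 1732 to 3961. The gene met17, of sulfur amino acid synthesis, held 447 reads against 5222 to 8710. Pericentromeric and telomere-linked helicase features entered through the higher library of each pair, which favours the direction of that library. Over 6 of them, the library labelled wild type lay above that labelled swd22 deletion by a median of 3.64. It lay above ssu72 by 2.503 over 6 and above the unnamed reference library by 3.42 over 6. It lay below the library labelled clr4 deletion by a median of -2.54 over 9. Every direction against this library below is drawn with that limit.

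**Figure D1:**
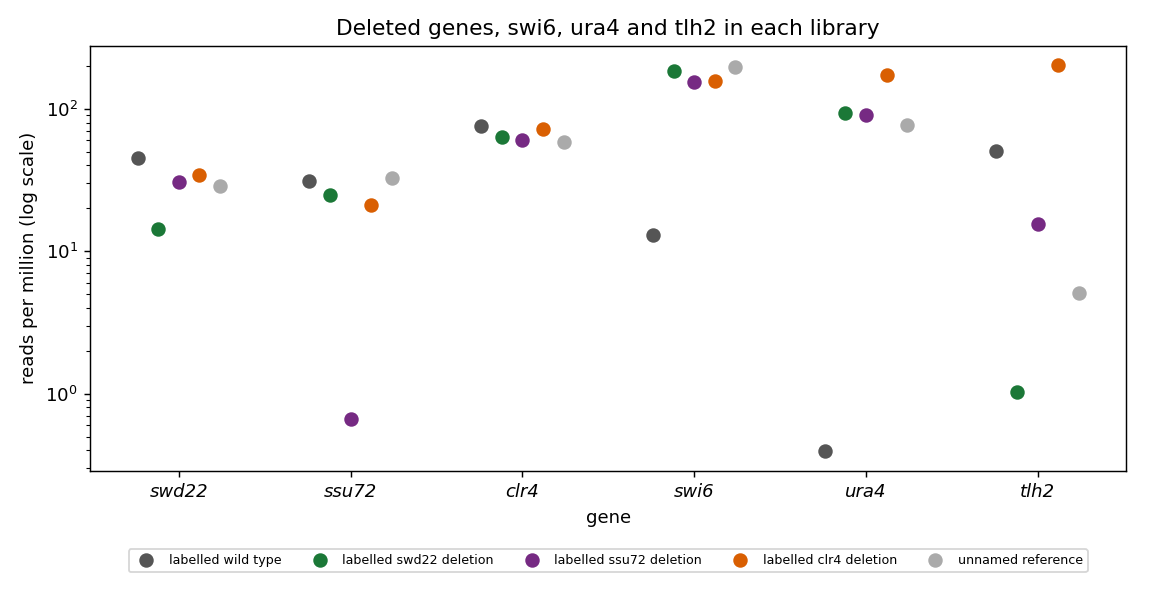
Reads scaled to library size on a log scale for the deleted genes and for swi6, ura4 and tlh2, with 1 point per library. The gene ssu72 was lowest in its own deletion library (16 reads), while swi6 (200 reads) and ura4 (6 reads) were lowest in the library labelled wild type.

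Deletion of swd22 asked which transcripts depend on this CPF subunit. Against the library labelled wild type, 634 of 6395 measured features were at least 2-fold higher and 186 lower, of which 327 and 87 were protein-coding. After ura4, the highest coding features were SPCC70.08c, a predicted methyltransferase, at 5.57 (5.30 to 5.85), the retrotransposon Tf2-11 (chromosome II, 4414657 to 4418658) at 5.34 (4.82 to 5.93), Tf2-2 at 4.96 (3.06 to 8.03), with only 2 reads in the library labelled wild type, and SPAC186.06 at 4.96 (4.31 to 5.70). SPAC6C3.03c at 4.82 (3.76 to 6.15), SPBC1271.08c at 4.71 (4.55 to 4.88), the dehydrogenase gene osr1 at 4.69 (4.51 to 4.87), the acetyltransferase gene aca1 at 4.52 (4.34 to 4.70) and hry1 at 4.52 (3.86 to 5.26) followed. All 4 measured Tf2 elements of 13 were higher, with a median of 4.33, above all 10000 random lists, although near-identical copies make the split between them uncertain. Among the lowest, the zinc transporter gene zrt1 differed by -2.83 (-2.87 to -2.80). The subtelomeric genes SPBC1348.06c and SPBPB2B2.15 held at most 4 reads against 111 and 53. They also held at most 4 reads in the libraries labelled ssu72 and clr4 deletion and 0 in the unnamed reference library. Only the library labelled wild type held more, so these differences are not particular to swd22.

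Phosphate response genes were lower in the library labelled swd22 deletion than in that labelled wild type. Of the 4 members, 3 were at least 2-fold lower, namely the acid phosphatase gene pho1 (chromosome II, 4446373 to 4449053) at -1.95 (-2.003 to -1.89), the phosphate transporter gene pho84 at -1.70 (-1.75 to -1.64) and the glycerophosphodiester transporter gene tgp1 at -1.44 (-1.56 to -1.32), while pho4 lay at 0.00 (-0.11 to 0.12). Their median of -1.57 was below all 10000 random lists. Against the unnamed reference library it was -1.08, also below all random lists, with 2 of 4 lower, and tgp1 turned to 0.95 (0.78 to 1.11). Telomere-linked helicase genes were lower too, with tlh2 (chromosome II, 4526885 to 4532899) at 20 reads against 771, a difference of -5.63 (-6.35 to -4.99), and a median of -5.36 over 3 measured members (percentile 0.005). Pericentromeric RNAs had a median of -2.73 over only 3 measured of 56 features (percentile 0.04), with SPNCRNA.373 at 6 against 31 reads. SPNCRNA.359 went the other way, at 30 against 12 reads, and the list mean was -1.59. Apart from SPNCRNA.359, with 32 reads in the unnamed reference library, the measured members of both groups were high in the library labelled wild type relative to that library, where tlh2 held 115 reads.

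Genes of replication and division, among them eng1 and agn1, which encode glucanases that part the daughter cells, were lower as a group. No member of the 19 was 2-fold higher and 8 were lower, with eng1 at -2.17 (-2.22 to -2.12), and the median of -0.89 was below all random lists. Core stress genes had a median of 0.23 (percentile 98.2), with 5 of 20 higher, led by the glutathione transferase gene gst2 at 3.43 (3.37 to 3.48) and the sulfiredoxin gene srx1 at 2.67 (2.49 to 2.84). Hexose and glucose-repressed genes went both ways around a median of 0.44 (percentile 98.0), with 4 of 15 higher and 3 lower. The invertase gene inv1 was at 3.58 (3.38 to 3.78), the hexose transporter gene ght5 at 2.02 (1.95 to 2.08) and the malic enzyme gene mae2 at -1.88 (-1.89 to -1.86). Mating and differentiation genes had a median of -0.18 (percentile 0.10) with 4 of 28 on each side, histone genes -0.38 (percentile 0.54) and ribosomal protein genes -0.23, below all random lists. None of the 11 histone or 131 ribosomal protein genes differed 2-fold. CPF and termination genes had a median of -0.18 (percentile 1.495), and swd22 was the only one of 23 at 2-fold.

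The remaining coding lists lay within 95% of random lists. DSR meiotic genes had a median of 0.11 (percentile 19.9), with mug8 at 1.004 (0.87 to 1.13), mcp7 at 0.95 (0.74 to 1.17) and mei4 at -0.33 (-0.55 to -0.12). Both mcp7 and mei4 turned against the unnamed reference library, to -1.89 (-2.02 to -1.77) and 0.27 (0.05 to 0.49). Heterochromatin factors had a median of 0.10 (percentile 63.8), with swi6 as the only 2-fold member. RNA elimination genes stood at -0.08 (20.8), iron acquisition at 0.04 (42.5), middle meiosis at 0.13 (40.5), nitrogen and amino acid transport at 0.20 (86.2) and subtelomeric features at 0.10 (9.62), in each case as median and percentile. By position, genes downstream of an SPNCRNA had a median of -0.03 (2.74), convergent pairs 0.04 (37.5) and tandem downstream genes 0.02 (3.04). The 6 mating-type genes in the files had no ratio in any file, which allows up to 4 reads in each library.

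Noncoding RNAs were more often higher than lower in the library labelled swd22 deletion than in that labelled wild type. Of 546 SPNCRNAs, 173 were higher and 25 lower, with a median of 0.59, above all random lists, with SPNCRNA.1255 at 5.33 (4.34 to 6.55) among the highest. Antisense features had a median of 0.26 (percentile 43.0), with 94 of 608 higher and 11 lower. Transfer RNAs had a median of -1.02, below all random lists, with 52 of 103 lower, and SPBTRNALEU.09 held 32 reads against 604. The snoRNAs had a median of 0.40 (percentile 99.5), snRNAs 0.32 (76.7), rRNAs 0.81 (88.8) and pseudogenes 0.30 (69.4). With the unnamed reference library as the control, medians were 0.12 for SPNCRNAs (percentile 86.6), with 114 higher and 90 lower of 566, 0.28 for tRNAs (97.2), with 37 higher and 23 lower of 103, 0.81 for mating genes (100), with 11 of 28 higher and none lower, 0.10 for histone genes (65.7) and 0.02 for CPF genes (29.6). Replication and division genes then stood at -0.30 (0.36) with 1 of 19 lower, core stress genes at 1.45 (100) with 13 of 20 higher, subtelomeric features at 1.32 (100) with 62 of 110 higher, pseudogenes at 0.96 (99.96) and tandem downstream genes at 0.03, below all random lists. Hexose and glucose-repressed genes stood at 1.29 (100) with 9 of 15 higher and none lower. Ribosomal proteins stood at -0.72, below all random lists, with 27 of 131 lower. The random lists also drew from noncoding features. Among coding features alone, the tandem list moved from percentile 3.04 to 19.0 against the library labelled wild type. No such percentile is given against the unnamed reference library. Of the calls, 320 higher and 34 lower features were shared with that control. Of 103 named features with known counts, 24 had the other direction against it, and 12 of the 70 at 2-fold did, among them tgp1, zrt1 at 0.41 (0.36 to 0.46) and SPBTRNALEU.09, with 2 reads there.

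The gene ssu72 encodes the CPF phosphatase. The library labelled ssu72 deletion had 681 of 6431 features at least 2-fold higher and 228 lower than that labelled wild type. Of these, 308 and 145 were protein-coding. After ura4, Tf2-11 at 6.70 (6.18 to 7.28) was the highest coding feature, followed by Tf2-2 at 5.79 (3.92 to 8.85), which had only 2 reads in the library labelled wild type, and shu1, a cell-surface heme protein gene (chromosome I, 85566 to 86324), at 5.65 (4.87 to 6.56). The median of the 4 measured Tf2 elements was 4.70, above all random lists. The lowest features included SPAC977.05c with at most 4 reads against 254, SPAC186.05c at -4.59 (-4.83 to -4.36) and the flocculin gene pfl7 at -4.50 (-5.04 to -4.002). SPAC977.05c was as low elsewhere, with 5 reads in the library labelled swd22 deletion and at most 4 in that labelled clr4 deletion. The unnamed reference library held 0 reads of it.

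Iron acquisition genes were higher in the library labelled ssu72 deletion, with a median of 0.51 (percentile 99.5), 4 of 13 at 2-fold higher and 1 lower. Beside shu1 the higher ones were the transporter gene str3 at 2.95 (2.39 to 3.56), the permease gene fip1 at 2.31 (2.07 to 2.55) and the multicopper oxidase gene fio1 at 2.25 (2.10 to 2.40). Mating and differentiation genes were lower, with 15 of 28 at 2-fold lower, 3 higher and a median of -1.004, below all random lists. Examples were mfm1, a pheromone precursor gene, at -3.10 (-3.91 to -2.36), rgs1 at -2.36 (-2.55 to -2.18) and mfm2 at -2.18 (-2.31 to -2.05). The meiosis regulator gene mei2 was at -1.89 (-2.02 to -1.77) here and at 0.81 (0.73 to 0.89) in the library labelled swd22 deletion. Phosphate response genes had a median of -1.54, below all random lists, with pho84 at -1.69 (-1.74 to -1.64), pho1 at -1.64 (-1.69 to -1.60) and tgp1 at -1.44 (-1.55 to -1.33). Against the unnamed reference library their median was -0.91 (percentile 0.01) with 2 of 4 lower, and tgp1 turned to 0.95 (0.79 to 1.11).

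Of 19 replication and division genes 11 were lower and none was higher, with a median of -1.11, below all random lists, and eng1 at -2.10 (-2.14 to -2.05). Core stress genes had a median of 0.23 (percentile 98.95), with 5 of 20 higher, led by gst2 at 3.76 (3.71 to 3.82), srx1 at 3.21 (3.04 to 3.38) and the metallothionein gene zym1 at 2.73 (2.56 to 2.90). CPF and termination genes had a median of -0.29 (percentile 0.50), in which ssu72 was the only 2-fold member. Lists within 95% of random lists were DSR meiotic genes at 0.28 (61.0), heterochromatin factors at 0.05 (68.7), RNA elimination at -0.20 (7.88), middle meiosis at -0.04 (7.31), histones at -0.32 (4.34), hexose and glucose-repressed genes at -0.08 (19.98), nitrogen and amino acid transport at 0.10 (74.2) and ribosomal proteins at -0.04 (82.4). Among the DSR genes meu32 was at 1.82 (1.40 to 2.27), mcp5 at 1.27 (1.06 to 1.48) and mcp7 at 1.23 (1.02 to 1.43). In the heterochromatin list arb2 was at -1.02 (-1.20 to -0.84).

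Telomere-linked helicase genes had a median of -1.71 (percentile 0.11) and a mean of -3.24 over 3 members, with tlh2 at 370 reads against 771, a difference of -1.71 (-1.89 to -1.53). Subtelomeric features had a median of -0.24, below all random lists, with 32 of 125 higher and 43 lower. Pericentromeric features had a median of -3.30 (percentile 0.07) and a mean of -1.77 over 3 members, of which SPNCRNA.359 was higher, with 57 reads against 12. Of 569 SPNCRNAs, 203 were higher and 18 lower (median 0.64, above all random lists), and of 613 antisense features, 139 were higher and 10 lower (median 0.42, above all random lists). The rRNAs had a median of -3.23 (percentile 0.02) over 4 features, with SPRRNA.52 at 191 reads against 2256. The tRNAs had a median of -0.67, below all random lists, snoRNAs 0.24 (95.3), snRNAs 0.29 (76.35) and pseudogenes 0.40 (81.9). By position, genes downstream of an SPNCRNA stood at -0.06 (8.11), convergent pairs at -0.03 (0.985) and tandem downstream genes at -0.03 (2.105), and the means of the last pair had the other sign, at 0.03 and 0.05. Among random lists of protein-coding features alone, the medians of these 2 lists fell at percentiles 40.5 and 36.5.

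Against the unnamed reference library, the medians in the library labelled ssu72 deletion were 1.11 for subtelomeric features (percentile 100), with 58 higher and 14 lower of 111, 0.62 for tRNAs (100), with 43 higher and 15 lower of 107, 0.03 for mating genes (38.1), with 4 higher and 1 lower of 28, 0.18 for SPNCRNAs (66.4), with 138 higher and 71 lower of 582, and -0.04 for CPF genes (35.2). Replication and division genes stood at -0.44 (0.01) with 4 of 19 lower, core stress genes at 1.46 (100) with 11 of 20 higher, hexose and glucose-repressed genes at 0.78 (99.9) with 6 of 15 higher, ribosomal proteins at -0.50, below all random lists, snoRNAs at 0.62 (99.95) and pseudogenes at 1.18 (99.98). Only 2 telomere-linked helicase genes and 1 pericentromeric feature passed the read filter against it, in this library and in that labelled swd22 deletion, and no list median was taken. The direction of tlh2 turned for ssu72, with 370 reads against 115 in the reference library, a difference of 1.60 (1.30 to 1.92), and stayed for swd22 at -2.31 (-3.08 to -1.62). Of the calls, 369 higher and 54 lower features were shared with that control. Of 100 named features with known counts, 28 had the other direction against it, and 16 of the 73 at 2-fold did, among them mcp7 at -1.62 (-1.73 to -1.51), mfm1 at 0.50 (-0.63 to 1.69) and mfm2 at 0.05 (-0.12 to 0.21).

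Deletion of clr4 removes the methyltransferase on which heterochromatin rests, and it addressed which transcripts are silenced by it. The library labelled clr4 deletion had 597 of 6442 features at least 2-fold higher and 144 lower, of which 273 and 62 were protein-coding. All 6 measured pericentromeric features of 56 were higher, with a median of 3.36, above all random lists, or 2.64 with zero counts at their bound and open counts at 4 reads. Only 3 were measured in the comparisons of swd22 and of ssu72. Features that passed the read filter through the library labelled clr4 deletion alone were higher by construction. SPNCRNA.231 (chromosome I, 3761023 to 3762114) held 160 reads against 9, a difference of 3.57 (2.61 to 4.73), and SPNCRNA.232 held 30 against 0, at least 6.69-fold higher. Telomere-linked helicase genes were higher with a median of 2.003 (percentile 99.6), and tlh2 held 4618 reads against 771, a difference of 2.003 (1.89 to 2.11). Subtelomeric features had a median of 0.42 (percentile 99.6), with 40 of 129 higher and 23 lower, and their higher members included hry1 at 6.05 (5.40 to 6.78). All 4 measured Tf2 elements were higher with a median of 3.29, above all random lists.

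Stress genes stood out in the library labelled clr4 deletion. Of 20 core stress genes 12 were at least 2-fold higher and none was lower, with a median of 1.20, above all random lists. The heat shock genes ssa1, of the Hsp70 family, at 3.62 (3.52 to 3.72) and hsp16 at 3.04 (2.95 to 3.13) led them together with gst2 at 3.21 (3.15 to 3.27). Hexose and glucose-repressed genes had a median of 1.14, above all random lists, with 8 of 15 higher and 1 lower, among them inv1 at 3.72 (3.53 to 3.92), the fructose bisphosphatase gene fbp1 at 2.98 (2.74 to 3.23) and the glycerol dehydrogenase gene gld1 at 2.81 (2.66 to 2.97). Of the phosphate genes pho1 was at 1.47 (1.43 to 1.496), pho84 at 0.52 (0.49 to 0.56) and tgp1 at -0.47 (-0.56 to -0.37), with a list median of 0.42 (percentile 96.4). Against the unnamed reference library tgp1 turned to 1.92 (1.78 to 2.07). Mating and differentiation genes had a median of -0.41, below all random lists, with 9 of 28 lower, such as isp4 at -2.62 (-2.76 to -2.50). Nitrogen and amino acid transport genes had a median of -0.27 (percentile 0.32), with the transporter gene put4 at -1.58 (-1.80 to -1.35). Replication and division genes had a median of -0.34 (percentile 0.05) with 3 of 19 lower, and ribosomal protein genes -0.17 (percentile 0.11) with none of 131 at 2-fold.

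Further lists lay within 95% of random lists in the library labelled clr4 deletion. DSR meiotic genes stood at 0.16 (38.7), CPF and termination genes at -0.19 (3.26), heterochromatin factors at -0.01 (66.8), RNA elimination at -0.15 (14.1), iron acquisition at 0.11 (80.4), middle meiosis at 0.07 (27.3), histones at 0.07 (85.5), genes downstream of an SPNCRNA at -0.02 (67.2), convergent pairs at -0.04 (6.78) and tandem downstream genes at -0.04 (7.92). The dicer gene dcr1 was at 0.65 (0.55 to 0.75), or -0.10 (-0.18 to -0.03) against the unnamed reference library, and meu32 at 1.33 (0.89 to 1.79). Of 577 SPNCRNAs 210 were higher and 11 lower, with a median of 0.72, above all random lists. Antisense features had a median of 0.27 (40.4), snoRNAs -0.07 (18.1), snRNAs 0.51 (90.6), rRNAs 0.16 (37.3) and pseudogenes 0.52 (94.3), whereas tRNAs stood at -1.18, below all random lists. With the unnamed reference library as the control, medians were 0.18 for SPNCRNAs (percentile 77.3), with 143 higher and 49 lower of 592, 0.33 for tRNAs (98.2), with 35 higher and 24 lower of 105, 0.19 for mating genes (88.5), with 7 higher and 1 lower of 28, and 0.05 for replication and division genes (71.7). Phosphate response genes then stood at 0.87 (98.8), histones at 0.52 (99.7), snoRNAs at 0.49 (99.9), pseudogenes at 1.58 (100), genes downstream of an SPNCRNA at 0.07 (98.4), convergent pairs at -0.03 (0.17) and tandem downstream genes at -0.04 (0.30). Core stress genes stood at 2.03 (100) with 18 of 20 higher and hexose and glucose-repressed genes at 1.58 (100) with 10 of 15 higher. Ribosomal proteins stood at -0.61, below all random lists, with 17 of 131 lower. The random lists drew from noncoding features too. No percentile among coding features alone is given for the lists by position against the unnamed reference library. Of the calls, 317 higher and 31 lower features were shared with that control. Of 115 named features with known counts, 30 had the other direction against it, and 10 of the 71 at 2-fold did, among them SPBPB7E8.01 at 0.06 (0.02 to 0.11).

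**Figure D2:**
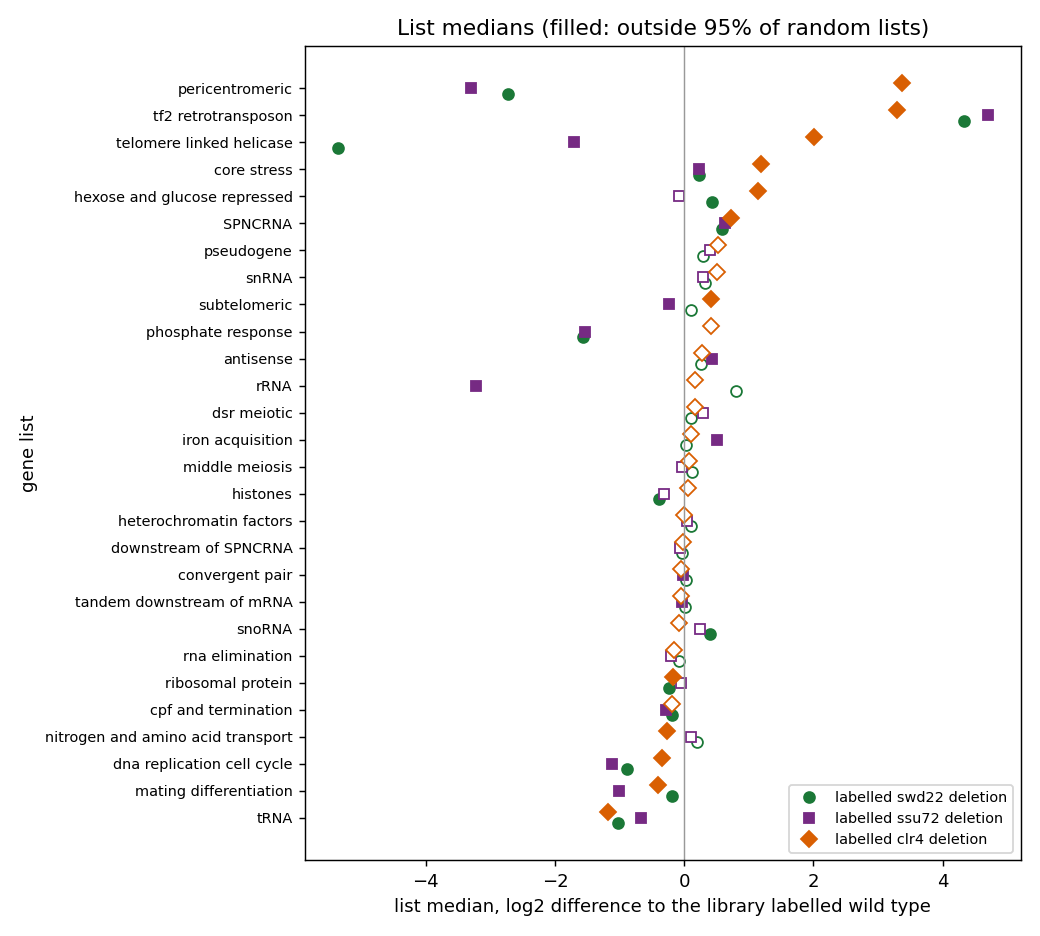
List medians of the log2 difference to the library labelled wild type, with 1 point per mutant library and filled points outside 95% of random lists. Tf2 elements were high in all 3 (4.33, 4.70 and 3.29), while telomere-linked helicase genes were low in the libraries labelled swd22 and ssu72 deletion (-5.36 and -1.71) and high in that labelled clr4 deletion (2.003).

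The mutants were then set side by side. Features at least 2-fold higher in all 3 numbered 323, of which 152 were protein-coding, and 72 were lower in all 3, of which 29 were protein-coding. Besides ura4 and Tf2-11, the shared higher genes included osr1, SPCC663.08c, another short chain dehydrogenase gene, SPBC1271.08c, and caf5, a spermine transporter gene. The shared lower genes included zrt1 and SPBPB7E8.01, a predicted cell surface protein gene. The libraries labelled swd22 and ssu72 deletion shared 505 higher features, where independent calls give 64.6. Counting error with a shared, unchanged control gave a median of 6 and at most 13 over 100 draws. They shared 136 lower features against 6.64, 2 and 5. For swd22 and clr4 the shared numbers were 354 higher (54.9, 6 and 13) and 87 lower (4.20, 2 and 5), and for ssu72 and clr4 they were 388 higher (58.8, 7.5 and 16) and 98 lower (5.13, 2 and 6). The draws held all libraries at the same read rates, so they do not show what a control that truly differs would give. The control is 1 library and could not be split, so part of the excess may come from it. Of the 305 shared higher features measurable against it, the unnamed reference library was also 2-fold above the library labelled wild type for 37.7%, and it was 2-fold below for 80.6% of the 72 shared lower features.

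Differences correlated across features between mutants, with genes not being independent replicates. Pearson's r was 0.888 for swd22 and ssu72 (Spearman 0.877), 0.737 for swd22 and clr4 (0.725) and 0.763 for ssu72 and clr4 (0.745), where unchanged libraries with the same control gave 0.628, 0.625 and 0.654. The covariances were 0.645, 0.443 and 0.488 against 0.0159, 0.0158 and 0.0163 in the unchanged libraries. Over 4857 protein-coding genes with at least 50 reads in every library, the standard deviation of the log2 difference was 0.257 between the libraries labelled swd22 and ssu72 deletion, 0.387 and 0.396 between these and that labelled clr4 deletion, and 0.514 to 0.611 between the mutants and the library labelled wild type. It was 0.710 to 0.722 between the mutants and the unnamed reference library, and 0.590 between the latter and the library labelled wild type.

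**Figure D3:**
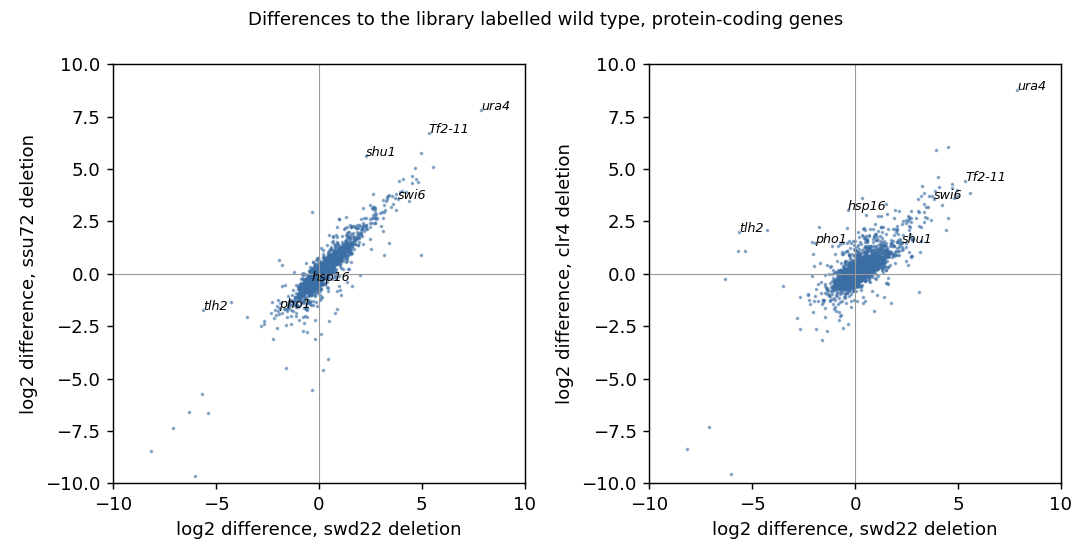
Log2 differences to the library labelled wild type, with swd22 set against ssu72 and against clr4. Each point is 1 protein-coding gene that passed the read filter in both mutants. Points lay along the diagonal in each panel, and over all features Pearson's r was 0.888 and 0.737, part of which comes from the shared control.

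Direct comparisons between mutants do not use the library labelled wild type. Between the libraries labelled ssu72 and swd22 deletion, 83 of 6415 features were at least 2-fold higher in the former and 84 lower. Higher in ssu72 was tlh2 at 3.92 (3.27 to 4.65), while SPNCRNA.293 at -5.79 (-6.67 to -5.03), SPAC186.05c at -4.79 (-5.03 to -4.56) and the rRNA feature SPRRNA.53, with only 2 reads against 385, were lower. The library labelled swd22 deletion was higher than that labelled clr4 deletion for 145 of 6442 features and lower for 214. The amino acid transporter gene SPBPB2B2.01 at 3.98 (3.65 to 4.32) and the oxygenase gene isp7 at 3.16 (3.05 to 3.27) were higher in the former, and tlh2 at -7.63 (-8.35 to -7.004) and SPNCRNA.231, with 0 reads against 160 and at least 45.8-fold lower, were lower. For ssu72 against clr4, 158 of 6458 features were higher and 202 lower, with shu1 at 4.17 (3.78 to 4.596) among the highest and SPAC750.05c, of the 5Tm protein family, at -6.82 (-8.13 to -5.77) among the lowest. The noncoding SPNCRNA class was lower for 77 and higher for 28 of 585 in swd22 against clr4, and lower for 63 and higher for 36 of 595 in ssu72 against clr4.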

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

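All tests of explanations in this part were chosen after the results were seen.

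The gene tlh2 differed between mutants in direction against the library labelled wild type, at -5.63 for swd22, -1.711 for ssu72 and 2.003 for clr4, a difference that was not tested. Against the unnamed reference library tlh2 stood at -2.31, 1.60 and 5.32 in that order. The gene pho1 did so at -1.95 for swd22, -1.64 for ssu72 and 1.465 for clr4, likewise untested.

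The genes swi6 and ura4 were far lower in the library labelled wild type than in the other 4 libraries. Lower depth is argued against, because at most 8.42% of the reads that depth alone would give were present. A loss of reads from the wider region around swi6 is argued against by the 2 neighbours on each side, of which the lowest stood at 0.34 relative to the other libraries where swi6 stood at -3.71. Beside ura4, at -7.86, the lowest was new25 at -1.24 and the others stood at -0.47 to 0.01, so a loss from the wider region is argued against there too. Pericentromeric and telomere-linked helicase features were pooled into 1 list. Over it, the library labelled wild type lay above the swd22, ssu72 and reference libraries by medians of at least 2.503. The read filter can be met through the library labelled wild type alone, which favours this direction. In the reference library only tlh2, SPAC212.06c and SPNCRNA.359 held at least 10 reads, at 115, 48 and 32 against 771, 105 and 12. The medians therefore cannot decide whether the library labelled wild type holds cells with another genotype and with reduced silencing. Directions at silenced regions against that library depend on this question. Against the unnamed reference library tlh2 stayed lower for swd22 (-2.31) and higher for clr4 (5.32) but turned for ssu72 (1.60). Subtelomeric medians stayed higher for swd22 (1.32) and clr4 (1.58) and turned for ssu72 (1.11). No biological explanation from the design was tested.

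A region of chromosome II (2109254 to 2139540), whose bounds were set after its values were seen, held 6387 reads of the unnamed reference library over 8 features that had 0 reads in all 4 libraries. With antisense features set aside, deletion of the whole region is argued against by its 3 features with several exons, which all kept reads in the 4 libraries, at least 84 each, although these were 0.36% to 13.0% of their level in the reference library. Deletion of the inner stretch alone (2110485 to 2125438), from the first to the last feature at 0, is argued against by rpt6 only, the 1 such feature wholly inside it, which held 316 to 785 reads. Of the single-exon features 6 of 7 were at 0, but the region was chosen by its features at 0. That share therefore cannot test the idea of reads shared with a 2nd copy in the sequence used for alignment, with spliced reads kept. Such a copy would take reads of the reference library too if that library was aligned in the same way, which is not known. The exception, SPBC23G7.14, held 8 to 16 reads and overlaps the spliced gene rpp202. The region holds mating-type genes, and no biological explanation was tested.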

How the results depend on the processing

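The use of the unnamed reference library as the control, the pseudocount of 1, open counts set to 4 reads and random lists of protein-coding genes were chosen after seeing the data. Fold thresholds and the restriction to protein-coding features change counts by construction. At 1.5-fold the counts higher and lower were 1243 and 468 for swd22, 1259 and 563 for ssu72, 1098 and 323 for clr4, 260 and 202 for ssu72 against swd22, 486 and 509 for swd22 against clr4, and 467 and 485 for ssu72 against clr4. At 4-fold they were 179 and 47, 209 and 63, 162 and 32, 20 and 27, 24 and 53, and 21 and 60 in that order. With protein-coding features only, the first 3 were 327 and 87, 308 and 145, and 273 and 62. Shared features of swd22 and ssu72, swd22 and clr4, and ssu72 and clr4 numbered 1008 and 324, 742 and 193, and 800 and 204 at 1.5-fold, 145 and 33, 95 and 15, and 101 and 19 at 4-fold, and 251 and 73, 165 and 31, and 175 and 45 among protein-coding features.

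With the unnamed reference library as the control, list medians outside 95% of random lists changed sign for swd22 in CPF genes (0.025), mating genes (0.81), histones (0.10) and tRNAs (0.28), for ssu72 in mating genes (0.026), subtelomeric features (1.11) and tRNAs (0.62), and for clr4 in mating genes (0.19), replication and division genes (0.054) and tRNAs (0.33). Among such lists, means had the other sign for ssu72 in convergent pairs (0.026) and tandem downstream genes (0.047). The cause was not tested. Of the other comparisons of counts and correlations with an alternative, 93 stayed within the range set for them, and of the list values 292 moved by less than 0.5 and 28 by more. These include 26 and 6 that changed sign in lists within 95% of random lists. The 6 were the medians against the reference library of rRNAs for swd22 (0.81 to -0.18), histones (-0.32 to 0.19) and hexose genes (-0.081 to 0.78) for ssu72 and snoRNAs for clr4 (-0.073 to 0.49), and the means of pseudogenes for swd22 (-0.53) and ssu72 (-0.19). With random lists of protein-coding features the coding lists outside 95% went from 10 to 8 for ssu72, without convergent pairs and tandem downstream genes. Open counts at 4 reads gave 679 higher features for ssu72 and a pericentromeric median of 2.85 for clr4. The split of higher and lower calls moved from 77.3% to 72.8% higher for swd22 with centring. Lists outside 95% of random lists numbered 14, 16 and 12 for swd22, ssu72 and clr4, and 11, 15 and 16 with the reference library as the control. TMM scaling had been planned for count files and was not run, since the scale of the deposited ratios was kept. No paired analysis was possible because each group had 1 library. Depth limits features with few reads, among them the pericentromeric ones.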

Other observations

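The tests of explanations in this part were chosen after the results were seen.

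The ammonium transporter gene amt3 stood at 3.19 in the library labelled swd22 deletion, 3.06 in that labelled ssu72 deletion and 1.58 in that labelled clr4 deletion, while the predicted acetate transporter gene mug86 stood at -1.51, -1.62 and -1.24. Among flocculin genes, pfl7 at -3.14 and pfl9 at -2.73 were among the lowest in the library labelled clr4 deletion, while against the unnamed reference library pfl9 stood at 0.27.

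Against the unnamed reference library, silenced regions lay further from the library labelled clr4 deletion than they did against the library labelled wild type. The list medians were 5.44 for pericentromeric features, 5.09 for telomere-linked helicase genes and 1.58 for subtelomeric features. Of the measured members of the first 2 lists, only SPNCRNA.359, tlh2 and SPAC212.06c held at least 10 reads in the reference library. The others passed the read filter through the library labelled clr4 deletion alone. For subtelomeric features the shift was not particular to clr4. Their medians against the reference library were 1.32 for swd22 and 1.11 for ssu72, where the library labelled wild type gave 0.10 and -0.24.

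The 3 mutant libraries shared 323 higher and 72 lower features. Counting error of the shared library is argued against, since simulated unchanged libraries shared at most 8 higher and 4 lower features. The reference library was 2-fold or more below the library labelled wild type too for 80.6% of the lower features, so the library labelled wild type alone may be out of line for these. Over coding genes at large the mutants lay closer to it than to the reference library, with standard deviations of 0.514 to 0.611 against 0.710 to 0.722. Of the higher features 37.7% were 2-fold above it in the reference library and 89 of 305 lay on the other side, so a shared effect of the deletions and a difference of that library cannot be told apart for them.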
